A study of Mus musculus with 4 samples.

How the data were processed

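Total RNA was extracted with Trizol from 4T1Br cells (4T1 in the sample titles) that carried a control hairpin or a hairpin against YTHDF3 after puromycin selection, and biotin-labelled RNA was hybridised to Affymetrix arrays, per the labels' protocols. The 4 arrays fell into shControl (2) and shYTHDF3 (2) by their titles. The deposited values are 1 number per probe set and array, normalised by the authors with RMA per the submitters' processing notes; the software and version are not given in the sources used here. RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a set, so a shift of most genes in one direction would not be seen. The deposited values were taken as log2 because RMA gives that scale and the range of the values fits it; the log base itself is not given in the sources used here. No depth applies to arrays, and their number limits the precision.

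The table held 41345 probe sets. The platform annotation gave 23521 of them 1 gene symbol, 1814 several and 16010 none. Of those with 1 symbol, 23328 matched a RefSeq gene by Entrez identifier and took its current symbol, and 193 kept the annotation's symbol. No gene was named from a probe set with several. The named probe sets stood for 22180 genes, 1082 of which had more than 1 probe set; a gene's value was that of its probe set with the highest mean over the 4 arrays. The background level was the 95th percentile of the means of 1108 olfactory receptor probe sets, log2 4.28. The 13056 genes with a mean above it were tested and 9124 were left out. Probe sets without a symbol or with several were tested separately. No genome coordinates are given, since the annotation's build is not stated in the sources used here.

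Groups were compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Changes are differences of group mean log2 values, shYTHDF3 minus shControl, with limma's moderated standard error (SE). The 24 gene lists, the named-gene rule and the tests were fixed before the data were examined. Lists with at least 5 genes tested (23 of 24) were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry as alternatives, adjusted over the lists; Ythdf3 was left out of its list. Camera at an estimated correlation uses the residual degrees of freedom, which are few here, so its p-values can be large even where that correlation is low. Counts adjusted over the list alone used limma's p-values of that list's genes. Another 5 gene families were chosen after the data were seen and adjusted among themselves.

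The genes named were, first, Ythdf3, Ythdf1, Ythdf2, St6galnac5, Gja1, Egfr and Vegfa whatever their values. Second came the 12 largest rises and the 12 largest falls among genes past the threshold whose shYTHDF3 values both lay on one side of both shControl values, leaving out gene models without a proper name, microRNA and small nucleolar RNA genes, and olfactory, vomeronasal and antigen receptor genes. Last came, for each list, up to 3 risers and 3 fallers past the threshold or, with none, the 2 genes with the largest absolute change. Ythdf2 was not analysed here.

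The alternatives were no filter, a filter at the median of all probe sets, an intensity trend with and without robust estimation, quantile normalization once more, a common median, the mean of all probe sets of a gene, the replicate number as a block, all probe sets past the filter, and leaving out each array in turn. With 1 array left out, the lone array of its group was assumed to vary like the arrays of the other group.

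The steps were tested on simulated data: 20 sets of 13056 genes, 200 of them changed, in the same 2 against 2 design. The limma step recovered 1.45% of genes changed by log2 0.5 and 76.1% of those changed by log2 1, the sign was right for 100% of those recovered, and 4.94% of its calls were false. The simulated variances were drawn from the model that limma fitted to these data, with no dependence on intensity. The false share therefore follows from that model and does not show the share in the real data. Recovery, too, holds for 200 changed genes. A shifted list was called in 10 of 10 sets, and an unshifted list in 0 of 10. The simulated genes were drawn independently of each other, whereas genes of some real lists moved together. Estimated correlations ran from -0.078 for neural and glial markers to 0.606 for hypoxia and glycolysis. The simulation therefore cannot show how often a list of genes that move together is called falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.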

Results

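Gene expression was measured in 4T1Br cells, a brain-seeking derivative of the mouse mammary carcinoma line 4T1, after lentiviral transduction with a control hairpin (shControl) or a hairpin against YTHDF3 (shYTHDF3). YTHDF3 is a cytoplasmic reader protein that binds N6-methyladenosine, or m6A, in messenger RNA. Each group held 2 arrays. The sample titles give the line as 4T1, and the cell line label and protocols give it as 4T1Br, the name used here. The comparison asked which transcripts differed in abundance between cells with the control hairpin and cells with the YTHDF3 hairpin; arrays read RNA abundance, not translation or protein. Median expression over all probe sets was 4.42 and 4.47 (log2) on the shControl arrays and 4.43 and 4.42 on the shYTHDF3 arrays. The number of arrays limits the precision. The labels do not say that the arrays came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

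Ythdf3, the targeted transcript, was lower on both shYTHDF3 arrays. Its probe set (17396178) read 8.98 and 8.81 in shControl and 8.21 and 8.16 in shYTHDF3, a log2 change of -0.71 (SE 0.10, limma adjusted p = 0.0355), which left 61.1% of the shControl level. Its paralog Ythdf1 differed by -0.13 (SE 0.09, limma adjusted p = 0.470), and a second Ythdf1 probe set by -0.11. Ythdf2 was not analysed here. Among genes tied to brain metastasis, Gja1, which encodes the gap junction protein connexin 43, fell by 0.93 (SE 0.09, limma adjusted p = 0.0217). Egfr, the epidermal growth factor receptor, fell by 0.70 (SE 0.11, limma adjusted p = 0.0417). Vegfa, the vascular endothelial growth factor, differed by -0.61 (SE 0.13) and did not pass the test (limma adjusted p = 0.0668, and 0.00482 with an intensity trend). The sialyltransferase gene St6galnac5 read 3.62 in shControl and 3.33 in shYTHDF3, below the background level of 4.28 in both, and was not tested. The Ythdf3 change lay between -0.79 and -0.63 when 1 array was left out, with limma adjusted p of 0.158 without shControl 1, 0.177 without shControl 2, 0.141 without shYTHDF3 1 and 0.188 without shYTHDF3 2. The Ythdf3, Gja1 and Egfr calls also ended without the filter on dim probe sets, at limma adjusted p of 0.0866, 0.0503 and 0.0979.

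Of 13056 genes tested, 356 changed, 167 being higher and 189 lower in shYTHDF3, and 76 of them changed at least 2-fold (27 higher, 49 lower). In 8 of the 356 a group mean lay under the background, and with that mean set to the background 73 changed at least 2-fold (26 higher, 47 lower). The deepest fall was that of Dcn, which encodes the matrix proteoglycan decorin, from 7.34 ± 0.14 to 4.68 ± 0.16 (SD, n = 2 each), a log2 change of -2.65. Nos2, the inducible nitric oxide synthase, fell by 2.36, and Ccl9, a chemokine, fell by 2.22. F5, coagulation factor V, fell by 2.14 from a level of 10.42. Angptl4, a secreted inhibitor of lipoprotein lipase, fell by 2.08, and Saa3, an acute-phase serum amyloid, fell by 2.05. Ptgs2, the inducible cyclooxygenase, fell by 1.95 and Cfb, complement factor B, fell by 1.94. Anxa8, an annexin, fell by 1.76, Cebpd, an acute-phase transcription factor, fell by 1.75, and Jag1, a Notch ligand, fell by 1.69. Stfa3 fell by 2.18 to a level of 3.87, under the background of 4.28, so its fall is given only as at least 1.77; the stefin A genes are near-identical copies, so which of them this probe set measured is uncertain. The limma adjusted p of these 12 falls lay between 0.00474 and 0.0240.

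The largest rise was that of Cyp24a1, the vitamin D 24-hydroxylase, from 5.03 ± 0.44 to 6.94 ± 0.02 (SD, n = 2 each), a log2 change of 1.91. Perp, a p63- and p53-regulated component of desmosomes, rose by 1.81, and Krt7, a keratin of simple epithelia, rose by 1.50. Gdpd5, a glycerophosphodiester phosphodiesterase, rose by 1.54. Txnip, the thioredoxin-interacting protein, rose by 1.46, its 2 shControl values being 7.39 and 6.77. Chn1 (a Rac GTPase-activating protein) rose by 1.37, Slc4a11 (a membrane transporter) by 1.36, Trp53i11 by 1.36, Chrnb1 (a muscle acetylcholine receptor subunit) by 1.34, Egr1 (an immediate early transcription factor) by 1.34 and Myo1d (an unconventional myosin) by 1.33. Lsamp, a neural cell adhesion gene, rose by 1.51 from a shControl level of 3.77, under the background, so only a rise of about 1.00 to its shYTHDF3 level of 5.28 was measured above it, and its place among the 12 rests on the value under the background. The second probe sets of Lsamp and Chn1 lay below background on average and differed by 0.50 and 0.11; with the mean of its probe sets the Chn1 change was 0.74. The limma adjusted p of these 12 rises lay between 0.00553 and 0.0338. The rule that chose these 24 genes took only genes whose 2 groups did not overlap.

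**Figure D1:**
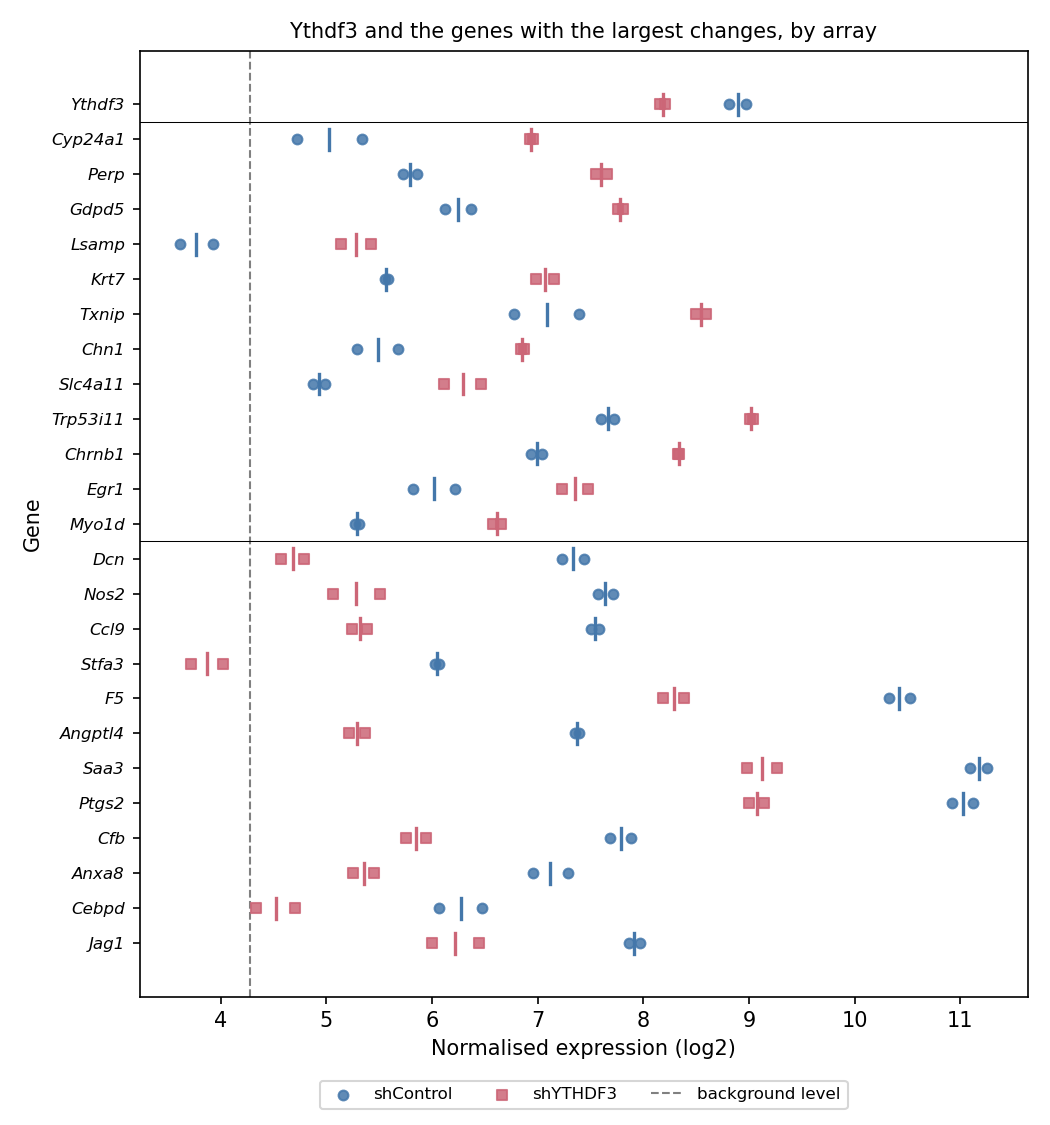
Normalised expression (log2, horizontal axis) of Ythdf3, the 12 genes with the largest rise and the 12 with the largest fall (vertical axis). Each circle is a shControl array, each square a shYTHDF3 array, short vertical bars are group means of 2 arrays and the dashed line is the background level of 4.28; groups that do not overlap were a condition for the 24 changed genes, and Dcn moves from 7.34 to 4.68.

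With any 1 of the 4 arrays left out, limma kept few or none of the 356 calls. Such a fit leaves fewer residual degrees of freedom, so this does not show how far the calls rest on that array. In all 356 genes the groups did not overlap, so leaving out an array could not turn the direction of a change. Dcn, Nos2, Ccl9, Stfa3 and Angptl4 were called without either shYTHDF3 array. Over all 21867 probe sets past the filter, named or not, limma called 0 (3337 at an unadjusted p under 0.05). Without the filter on dim probe sets, 41 of the 356 calls were kept, and an intensity trend in the variance model raised the count to 1426. With that trend 12 of the named genes described here as not passing did pass: Vegfa, Fmr1, Ifih1, Psmb10, Mcm5, Gins2, St3gal3, Ndufs7, Cycs, H2bc9, Cd68 and Map2.

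Genes of hypoxia and glycolysis were lower as a group in shYTHDF3. Of 28 tested, 3 fell and 25 did not pass over all genes, while 16 fell when adjusted over the list alone. Ero1a, an endoplasmic reticulum oxidoreductase induced by hypoxia, fell by 1.29, with -1.11 on its second probe set. Slc2a3, a glucose transporter, fell by 1.01, and Pfkfb3, whose product makes an activator of glycolysis, fell by 0.92. The list median was -0.38 (camera adjusted p = 2.45e-08; adjusted p = 0.411 with an estimated correlation). Stress-response genes were lower too: of 31 genes of the integrated stress and unfolded protein response, 3 fell and 28 did not pass. Ddit4, an inhibitor of mTORC1 signalling, fell by 1.33, and the mitochondrial folate enzyme gene Mthfd2 and the serine synthesis gene Psat1 fell with changes of -0.89 and -0.73. Adjusted over the list alone, 9 fell and 1 rose, with a list median of -0.22 (camera adjusted p = 2.63e-04; adjusted p = 0.411 with an estimated correlation), and of -0.14 without shYTHDF3 1.

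Genes associated with brain metastasis were lower as a group, with 8 of 21 falling, none rising and 13 not passing. Angptl4, Ptgs2 and Gja1 led the falls, at -2.08, -1.95 and -0.93. The list median was -0.39 (camera adjusted p = 1.26e-05; adjusted p = 0.345 with an estimated correlation), and 13 fell and 2 rose when adjusted over the list alone. Matrix proteases and their inhibitors shared the direction: 6 of 25 fell and 19 did not pass, while 12 fell when adjusted over the list alone. The metalloproteinase gene Mmp10 fell by 0.99, Mmp3 fell by 0.89, and Timp1, which encodes an inhibitor of metalloproteinases, fell by 0.77. Their list median was -0.27 (camera adjusted p = 7.77e-06; adjusted p = 0.345 with an estimated correlation).

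Cytokine and chemokine genes moved both ways, with 6 of 27 falling, 3 rising and 18 not passing. Ccl9 and Saa3, the latter an acute-phase serum amyloid that the list also held, led the falls with changes of -2.22 and -2.05. Csf3, the granulocyte colony-stimulating factor, fell by 1.00. Ccl20 and Cx3cl1, both chemokines, rose by 1.01 and 0.98, and Il18 by 0.56. The list median was -0.19 (camera adjusted p = 8.03e-04; adjusted p = 0.381 with an estimated correlation), and 10 fell and 3 rose when adjusted over the list alone. Among angiogenesis genes, 4 of 28 fell and 24 did not pass, led by Angptl4, Jag1 and the semaphorin gene Sema3c, at -2.08, -1.69 and -1.15; Sema3c ended at 4.08, under the background, which leaves a fall of at least 0.95. That list had a median of -0.18 (camera adjusted p = 0.00652; adjusted p = 0.345 with an estimated correlation); adjusted over the list alone, 10 fell and 3 rose.

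Epithelial genes were higher and mesenchymal genes lower in shYTHDF3. Of 21 epithelial genes, 5 rose and 16 did not pass; adjusted over the list alone, 10 rose and 1 fell. Besides Krt7, St14, which encodes the membrane protease matriptase, rose by 1.07, and Jup, the junction protein plakoglobin, rose by 0.87. The epithelial median was 0.25 (camera adjusted p = 4.94e-05; adjusted p = 0.345 with an estimated correlation), and 0.13 without the filter on dim probe sets. Of 24 mesenchymal genes, 2 fell and 22 did not pass; adjusted over the list alone, 3 fell and 2 rose. Ccn1, a matricellular protein gene, fell by 1.41, and Fn1, fibronectin, fell by 0.81. The mesenchymal median was -0.15 (camera adjusted p = 0.0275; adjusted p = 0.411 with an estimated correlation), and that call ended without shControl 2 (median -0.094; camera adjusted p = 0.0715) and without shYTHDF3 2 (median -0.096; camera adjusted p = 0.118).

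Genes of cholesterol synthesis and uptake were higher: 2 of 19 rose and 17 did not pass, while 8 rose when adjusted over the list alone. Insig1, which encodes a sterol-regulated membrane protein, rose by 1.22, and Cyp51, lanosterol demethylase, rose by 0.71. The median was 0.21 (camera adjusted p = 3.64e-05; adjusted p = 0.345 with an estimated correlation), and 0.32 without shYTHDF3 2. Translation initiation and elongation factors were slightly lower, with a median of -0.08 (camera adjusted p = 0.00834; adjusted p = 0.411 with an estimated correlation). The median was -0.047 without shControl 1 and -0.038 after repeated quantile normalization. Of these 41 factors, Eif2b3, a subunit of the eIF2B exchange factor, fell by 0.62 and 40 did not pass; adjusted over the list alone, 2 fell.

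A further 3 lists were higher by camera with no member past the limma test, nor any when adjusted over the list alone. Their counts at an unadjusted p under 0.05 stand against 1596 higher and 1354 lower among all 13056 genes tested by limma. Interferon-stimulated genes had a median of 0.12 over 26 genes, 7 of them higher at an unadjusted p under 0.05 (camera adjusted p = 0.00956; adjusted p = 0.411 with an estimated correlation); Ifih1 differed by 0.56 and Isg15 by 0.52. This call ended without shControl 1 (camera adjusted p = 0.117) and without shYTHDF3 2 (camera adjusted p = 0.0808), and the median was 0.21 without shControl 2. Cell cycle genes had a median of 0.13 over 38 genes, 8 of them higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0129; adjusted p = 0.497 with an estimated correlation); Mcm5 differed by 0.47 and Gins2 by 0.44. That call ended without shControl 2 (camera adjusted p = 0.0715) and without shYTHDF3 1 (camera adjusted p = 0.0643). Replication-dependent histones had a median of 0.11 over 9 genes, 3 of them higher at an unadjusted p under 0.05 (camera adjusted p = 0.0472; adjusted p = 0.557 with an estimated correlation). H2bc9 differed by 1.39, its 2 shYTHDF3 values being 5.48 and 6.66, and by 0.80 without shYTHDF3 2; H1f3 differed by 0.36. The histone call ended without shControl 1 (camera adjusted p = 0.0508), without shControl 2 (0.178) and without shYTHDF3 2 (0.336), with arrays shifted to a common median (0.0542) and with the filter at the median of all probe sets (0.0519); without shYTHDF3 1 the median was 0.18.

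**Figure D2:**
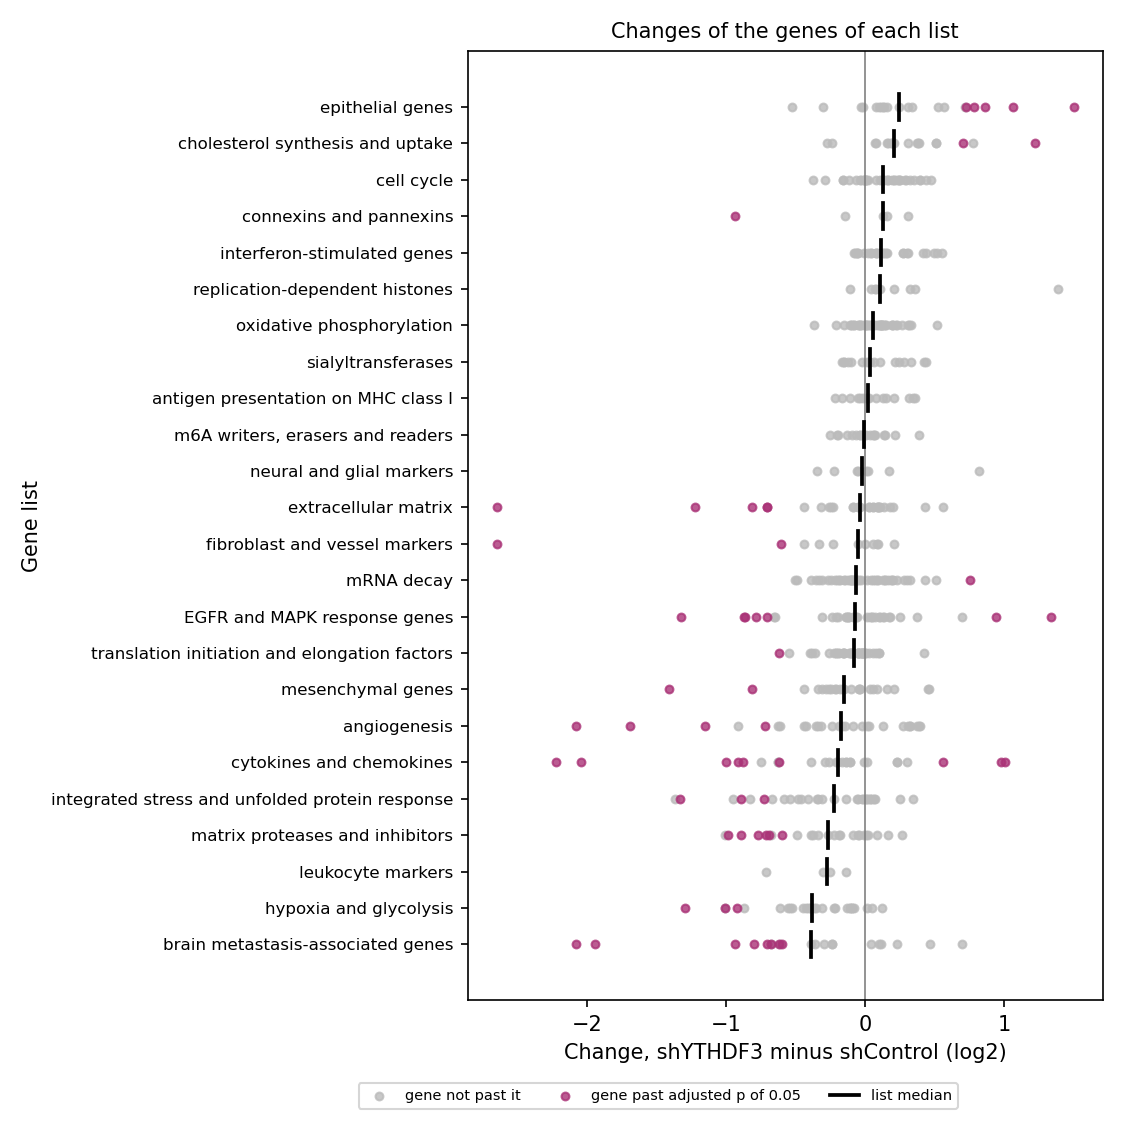
Log2 change (shYTHDF3 minus shControl, horizontal axis) of each tested gene of the 24 lists (vertical axis, ordered by list median), Ythdf3 left out. Each point is a gene, coloured where its adjusted p was under 0.05, and black bars are list medians, which run from -0.39 for brain metastasis-associated genes to 0.25 for epithelial genes.

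The other lists were not shifted by camera. Of 30 extracellular matrix genes, 5 fell and 25 did not pass (6 falling and 2 rising when adjusted over the list alone); Dcn fell by 2.65, Thbs2, a thrombospondin, fell by 1.22 and Fn1 fell by 0.81. The matrix median was -0.04 (camera adjusted p = 0.0855), 0.0011 after quantile normalization was applied once more, -0.019 with a common median and 0.042 without shControl 2; without shControl 1 the list passed (median -0.091; camera adjusted p = 0.00385), as it did with an intensity trend (0.0277) and with the mean of all probe sets of a gene (0.0251). Genes of the EGFR and MAPK response went both ways, 2 of 36 rising, 5 falling and 29 not passing (4 rising and 7 falling when adjusted over the list alone; median -0.07; camera adjusted p = 0.140). That median was -0.11 without shControl 1, -0.020 without shControl 2, 0.0043 without shYTHDF3 1 and -0.13 without shYTHDF3 2. Egr1 and Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 1.34 and 0.94, whereas Dusp1, a MAP kinase phosphatase, fell by 1.33 and Ier3 and Fosl2 each fell by 0.87. Of 46 mRNA decay genes, Pan2, a deadenylase subunit, rose by 0.75 and 45 did not pass (median -0.06; camera adjusted p = 0.555; 3 rising and 3 falling when adjusted over the list alone); with 1 array left out the median ran from -0.088 to 0.0013. Of 5 connexin and pannexin genes only Gja1 passed, also when adjusted over the list alone (camera adjusted p = 0.766); the list median was 0.13, while its mean of -0.10 and its test pointed down.

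The m6A writers, erasers and other readers had a median of -0.0084 over 19 genes, and limma called 0, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.935). Fmr1, an RNA-binding protein gene, differed by 0.39 and the methyltransferase gene Mettl16 by -0.25. The mean of this list was 0.0045, its test pointed down, and its median was 0.0032 after repeated quantile normalization and 0.012 with a common median. By limma none of 16 genes of antigen presentation on MHC class I passed (3 higher at an unadjusted p under 0.05; median 0.02, and 0.021 to 0.074 with 1 array left out; camera adjusted p = 0.479), with Psmb10 at 0.36 and Psmb9 at 0.34. Limma called none of 17 sialyltransferase genes (4 higher at an unadjusted p under 0.05; median 0.03; camera adjusted p = 0.197; fry adjusted p = 0.0245), with St6gal1 at 0.44 and St3gal3 at 0.42. The sialyltransferase median was -0.0045 without the filter, 0.12 without shControl 1, 0.090 without shControl 2, 0.068 without shYTHDF3 1 and 0.060 without shYTHDF3 2. None of 45 oxidative phosphorylation genes passed by limma (5 higher and 1 lower at an unadjusted p under 0.05; median 0.06; camera adjusted p = 0.113). In that list Ndufs7 differed by 0.52 and Cycs by -0.37, the probe sets of Cycs ranging from -0.53 to -0.29. Adjusted over the list alone, none of these 4 lists held a call. Over all 13056 genes tested by limma, 1596 were higher and 1354 lower at an unadjusted p under 0.05.

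Markers of other cell types were measured as a check on carried-over cells. Of 11 fibroblast and vessel markers above background, Dcn and Pdgfra fell, with changes of -2.65 and -0.61, and 9 did not pass (the same 2 calls when adjusted over the list alone; median -0.05, and -0.13 to -0.012 with 1 array left out; camera adjusted p = 0.0768). The Pdgfra call ended with a common median (limma adjusted p = 0.0508). This list passed without shControl 1 (camera adjusted p = 0.0251), without shYTHDF3 1 (0.0293) and with an intensity trend (0.0488). Of 20 leukocyte markers on the array 4 lay above background, too few for a list test; all 4 had negative changes (median -0.28), and by limma 0 passed, with 1 lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. Cd68, a lysosomal protein of macrophages, differed by -0.72 (limma adjusted p = 0.0547, and 0.0474 with the filter at the median) and Cd14 by -0.30. Of 8 neural and glial markers above background limma called 0, with 1 higher and 1 lower at an unadjusted p under 0.05, and 1 higher when adjusted over the list alone (camera adjusted p = 0.935). Map2 differed by 0.82 and Syt1 by -0.35, to 4.21, under the background; the median of -0.02 and the camera test pointed down and the mean of 0.04 up.

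In all, camera with the preset correlation called 13 of 23 lists, 5 higher and 8 lower. Some lists share genes, such as Angptl4 in the brain metastasis and angiogenesis lists, so these are not as many separate shifts. With an estimated correlation it called 0 (2 at an unadjusted p under 0.05), and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, called 7. Of these, 6 were also called by camera: brain metastasis-associated genes, matrix proteases, cytokines and angiogenesis as lower, and epithelial and cholesterol genes as higher. The other was the sialyltransferase list, higher by fry (adjusted p = 0.0245) and not called by camera.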

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

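All alternatives here were planned except those on the 5 gene families chosen after the data were seen. The count of calls depended on the settings. It was 488, 417, 408 and 386 with the filter at the median, repeated quantile normalization, a common median and the mean of all probe sets. It rose to 1426 with an intensity trend (730 higher, 696 lower) and 1465 with robust estimation added (755 higher, 710 lower). Without the filter it was 43 (14 higher, 29 lower, 42 at least 2-fold), over 22180 genes rather than 13056. Of those calls 32.6% were higher, against 46.9% with the filter. Nearly all of them were at least 2-fold, and of the 76 calls with the filter that changed as much, 27 were higher and 49 lower. The lower share thus went with larger changes, and no further cause was tested. In the fit over all probe sets past the filter, which called 0, the replicate SD of unnamed probe sets had a median of 0.214 against 0.101 for the genes tested. Leaving out 1 array gave 0 to 12 calls (0 to 1 higher, 0 to 11 lower, 0 to 12 at least 2-fold), with fewer samples in the fit.

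The Ythdf3 change was -0.71 without the filter (limma adjusted p = 0.0866) and -0.79 to -0.63 with 1 array left out; the adjusted p ranged from 9.38e-04, with trend and robust estimation, to 0.188. The replicate number as a block gave 51 calls (15 higher, 36 lower; 29.4% higher), 48 of them among the 356, and a Ythdf3 change of -0.71 (adjusted p = 0.0758); with it the histone list was not called (camera adjusted p = 0.0588) and the integrins were (0.0356). Deviations of arrays with the same number had a correlation of -0.066 across genes, which are not independent, and the labels do not tie the numbers to a shared culture. Of 55 named genes past the threshold, 26 kept their call without the filter, 28 with the block, 0 without either shControl array, 5 without shYTHDF3 1, 11 without shYTHDF3 2, 54 with a common median and 0 in the fit over all probe sets, which called none. With the mean of all probe sets 54 were kept, and Lsamp fell below background and was not tested; with the filter at the median, repeated quantile normalization and the intensity trend, with and without robust estimation, 55 were kept.

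The number of lists called was 10 to 15 across the refits, 7 by fry and 0 with an estimated correlation. No list past the threshold turned direction. Lists not past it whose test turned had these medians: connexins 0.10 without the filter; neural and glial markers 0.0040 with the filter at the median, -0.024 with an intensity trend, with and without robust estimation, -0.0061 with repeated quantile normalization and 0.0040 with the mean of all probe sets. With 1 array left out the medians ran from -0.041 to 0.025 for the m6A list, -0.080 to 0.21 for connexins, -0.051 to 0.036 for neural and glial markers and -0.10 to 0.091 for keratins. The causes were not tested. The background limits what can be said of dim genes: 9124 genes were below it.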

Other observations

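The 5 gene families, the tests of dish-to-dish culture state and of brightness, the count of splits and the condition on levels in the fibroblast test were chosen after the results were seen. The medium and fibroblast tests were written before they were run, but for patterns already seen in the results. Acute-phase and complement genes were lower in shYTHDF3: of 23 tested, 8 fell, 0 rose and 15 did not pass by limma (13 lower and 1 higher at an unadjusted p under 0.05). Besides Saa3, Cfb and Cebpd, the haptoglobin gene Hp fell by 1.53, Ptx3, a pentraxin, fell by 1.19 and Osmr, the oncostatin M receptor, fell by 1.16. Lbp, which encodes a lipopolysaccharide-binding protein, fell by 0.74, and Stat3, a transcription factor of the interleukin-6 response, fell by 0.62. The family median was -0.44 (camera adjusted p = 9.88e-10; adjusted p = 0.236 with an estimated correlation), and -0.19 over all family members without the filter. Since the family was drawn up after Saa3, Cfb and Cebpd were seen among the largest falls, its test is not independent evidence of the direction.

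Integrin genes moved both ways: Itga2, Itgb3 and Itgb7 fell with changes of -1.23, -1.22 and -0.56, Itga1 rose by 1.09, and 10 of 14 did not pass (median -0.23; camera adjusted p = 0.0522). The integrin test passed by camera adjusted p with an intensity trend (0.0439), without the filter (0.0486, median -0.10), with a common median (0.0452) and with the mean of all probe sets (0.0431). Without shControl 1 the integrin median was -0.15. Of 16 glutathione S-transferase genes, which encode detoxifying enzymes, Gsta4, Gstm1 and Gstm7 rose by 0.69, 0.67 and 0.67 and 13 did not pass (median 0.20; camera adjusted p = 0.0841; 7 higher and 3 lower at an unadjusted p under 0.05, 5 higher and 3 lower when adjusted over the family alone). Of 73 small nucleolar RNA genes, Snora74a and Snora34 fell with changes of -1.35 and -0.86, Snora62 rose by 0.72 and 70 did not pass. Their median was -0.14 (camera adjusted p = 0.00672, and 0.236 with an estimated correlation). The call ended without shYTHDF3 2 (median -0.070), and without shControl 2 the median was -0.094. These families too were chosen after the data were seen, so their tests are not independent evidence of a shift. Of 20 keratin genes only Krt7 passed by limma (camera adjusted p = 0.775), and the family median of -0.01 was 0.0082 with a common median. The fry adjusted p was 0.0202 for acute-phase genes and integrins, both down, and 0.0202 for glutathione S-transferases, up. Fry did not call the small nucleolar RNAs (adjusted p = 0.0871) or the keratins (adjusted p = 0.415).

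The lower hypoxia and glycolysis list was weighed against 3 technical explanations. Brightness of the listed genes was argued against: 0% of 10000 random lists matched on mean expression had a median as low as -0.38. The middle 95% of their medians lay between -0.095 and 0.082. The random genes were drawn singly, whereas the listed genes moved together (estimated correlation 0.606). The share therefore bears on brightness only and is no further test of the list. Dish-to-dish culture state, such as cell density or oxygen, may remain a candidate explanation: the list median differed by up to 0.113 between replicates, a ratio of 0.340 to the difference of 0.333 between groups. With 2 arrays per group, culture state and an effect of the hairpin cannot be told apart for this list. Fresher or less depleted medium in the shYTHDF3 dishes, a hypothesis prompted by the rise of the glucose-induced Txnip, was tested on Arrdc4, another glucose-induced gene. Arrdc4 differed by 0.31 (95% interval -0.10 to 0.72, limma adjusted p = 0.335), so this stays open, as does an effect of lower YTHDF3, for which no test was possible with 1 hairpin label.

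The fall of Dcn and other matrix genes was weighed against fewer carried-over fibroblasts in the shYTHDF3 dishes. The fibroblast transcripts Col1a1, Col1a2, Col3a1, Lum and Sparc had a median change of -0.041 (median absolute deviation 0.20), against the -1.33 that would be 50% of the fall of Dcn. That bound, set before this test was run but after the fall of Dcn was seen, decides nothing. Col1a1, Col1a2, Col3a1 and Lum read 5.16, 4.83, 4.40 and 2.68 in shControl, too near or under the background of 4.28 to show such a fall. The high level of Sparc, 10.33, would hide a small share of fibroblasts. Of the 11 fibroblast and vessel markers, Dcn among them, 7 had negative and 4 positive changes. Since these levels cannot decide the question, this explanation stays open. A change within the tumour cells, from lower YTHDF3, from another target of the hairpin or from culture state, stays open and was not tested.

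The 4 arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 356 genes (2950 at an unadjusted p under 0.05) and was the only 1 of the 3 splits to give as many. The highest other split gave 0 by limma (246 at an unadjusted p under 0.05). Each other split set 1 shControl and 1 shYTHDF3 array against the rest. A difference between the groups thus widened its spread and lowered its count, so those counts do not show what chance would give.

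Probe sets outside the comparison were tested on their own. Of 7140 without a gene symbol limma called 0 (560 at an unadjusted p under 0.05), and of 1011 with several symbols it called 0 (200 at an unadjusted p under 0.05). Among the 13056 genes tested, 2950 had an unadjusted limma p under 0.05. The 0 calls therefore do not show that none of these probe sets changed.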
